A study of Mus musculus with 3 samples.

How the data were processed

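Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used to map the histone deacetylase HDAC3 in mouse liver. Per the labels' protocols, livers came from male C57Bl/6 mice of 10 to 12 weeks, collected at zeitgeber time 10 (hours after lights on). The tissue was cross-linked with 1% formaldehyde, immunoprecipitation was run on lysates from 4 to 5 mice per condition, and the DNA was pooled before sequencing on an Illumina GAIIx. The series holds 3 samples: HDAC3 ChIP from wild-type (WT) liver, HDAC3 ChIP from NS-DADm liver, and an input sample with no antibody. Per the labels, the WT sample pools 2 wild-type samples, 1 of them from floxed-Hdac3 liver given an adeno-associated virus expressing GFP. The input sample has no processed file and was not analysed here. Each genotype is therefore represented by 1 pooled library, with no replicate error between mice.

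The authors deposited 1 peak list per genotype, with a position, a name and a value for each peak. The value was taken as RPM (reads scaled to the size of the library) because the names of the deposited files carry a limit of 1 RPM and the lowest values are 1.0 in WT and 1.1 in NS-DADm. The unit is not defined in the files, which have no header. The submitters' processing notes name HOMER and the mouse build mm8, without a version. The aligner, the peak-calling settings and any use of the input are not given in the sources used here. All peaks are 200 bp wide and all values are rounded to 0.1 RPM. Every 0.1 step from 1.0 to 5.0 RPM in WT and from 1.1 to 2.5 RPM in NS-DADm holds at least 1 peak, so the worth of a single read could not be recovered and the number of reads per library is unknown. No counting interval could be given for a single peak value.

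The WT value comes from a pooled sample, and a threshold in RPM does not remove differences in depth or in immunoprecipitation yield between libraries. A peak missing from a list can have been under 1 RPM or have been removed by another criterion, and the lists do not tell these apart.

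Peaks were compared with bedtools 2.31.1, and 2 peaks were called shared when they overlapped by at least 1 bp. Where an NS-DADm peak overlapped more than 1 WT peak, the WT peak with the nearest centre was paired with it. Shares of peaks carry exact Clopper-Pearson 95% intervals. These cover counting error over the peaks of these 2 lists only, since peaks are not replicates. Overlap by chance came from 1000 random placements of the NS-DADm peaks on their own chromosomes, within the span covered by peaks. WT peaks were ordered by their own value and split into 4 parts of like size. Median values were compared over peaks with a two-sided permutation test of 100000 resamples. Shares per chromosome and of clustered against isolated peaks (another WT peak within 10 kb, edge to edge) were compared with two-sided Fisher's exact tests, with Benjamini-Hochberg adjustment over the 20 chromosomes tested. Ratios of peak values at shared peaks are log2 ratios of the deposited RPM values, with no pseudocount, and their 95% intervals come from 2000 bootstrap resamples of peaks. Computations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and statsmodels 0.14.6. The overlap step was run on simulated data: of 600 simulated peaks, 400 were placed so that they overlapped WT peaks, and 400 were recovered. This checks the counting only, since the overlaps were set by the placement.

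Coordinates are on mm8 and counted from 1. The gene table at hand is of the later build GRCm38, and 38 peaks lie beyond the last gene of their chromosome in it. It was therefore not used to assign genes, and whether a peak lies in an exon, an intron or between genes was not analysed here. The gene lists that had been fixed for circadian clock, lipid, cholesterol, glucose and cell type marker genes were not tested for the same reason.

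Groups, gene lists, the rule for named regions, and the tests and alternatives not listed here as later additions were fixed before the data were examined. The regions named are the 10 highest WT peaks, the 5 highest NS-DADm peaks, the 5 highest peaks of each list with no overlap in the other, and the WT cluster with the most peaks. Alternatives covered other overlap rules, a threshold of 2 RPM, a WT list reduced to the size of the NS-DADm list, autosomes only, merging of peaks within 500 bp and other cluster distances. Both lists at 1.1 RPM or more, chromosomes 9 and 11 left out, clustering compared within the 4 parts of the WT list by value, shared pairs chosen by the NS-DADm value and high WT peaks counted whether or not they were listed in NS-DADm were added after seeing the data. So were the subset of WT peaks above 4 RPM, the correlation of values at shared peaks, and both tests of NS-DADm peaks with against without a WT peak, by their medians and by their share at 1.1 RPM and above 1.6 RPM.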

Results

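HDAC3 is a histone deacetylase that acts as the catalytic subunit of the NCoR and SMRT corepressor complexes, which nuclear receptors recruit to chromatin. The labels give only the name NS-DADm. As background knowledge of this mouse line, not stated in the sources used here, it carries mutations in the deacetylase-activating domain, the part of both corepressors that binds and activates HDAC3. The comparison of the 2 livers asks where HDAC3 is found on the genome with and without intact activating domains. The data are 2 lists of HDAC3 peaks, 1 from WT liver and 1 from NS-DADm liver, each from 1 pooled library, so no difference between genotypes could be tested against the spread between animals. Peak values are the authors' own and were taken to be in RPM, a unit that the lists themselves do not define.

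The NS-DADm list held far fewer HDAC3 peaks than the WT list, and their values were lower. The WT list held 5799 peaks covering 1160 kb and the NS-DADm list held 600 peaks covering 120.0 kb, a 9.67-fold difference in number. The last peak numbers in the names, summed over chromosomes, were 11772 in WT and 3703 in NS-DADm, a 3.18-fold difference, and peaks were listed for 49.3% and 16.2% of these numbers, whose meaning the sources used here do not give. The median peak value was 1.4 RPM in WT (interquartile range 1.2 to 1.9) and 1.2 RPM in NS-DADm (1.1 to 1.4). The difference widened with peak value. The WT list had 1222 peaks at 2 RPM or more, 21.1% of its peaks, and the NS-DADm list had 20, or 3.33%, a 61.1-fold difference. Above 4 RPM there were 62 listed WT peaks and 0 listed NS-DADm peaks, and the highest listed values were 7.6 and 3.9 RPM. Peak numbers were also skipped before the first listed peak of a chromosome, 354 in NS-DADm and 38 in WT. If these were higher candidates removed by another criterion, the NS-DADm maximum is that of the list only. The lowest listed value was 1.0 RPM in WT and 1.1 RPM in NS-DADm. At 1.1 RPM or more, a limit chosen after seeing the data, WT held 5324 peaks, 8.87 times the NS-DADm number.

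**Figure D1:**
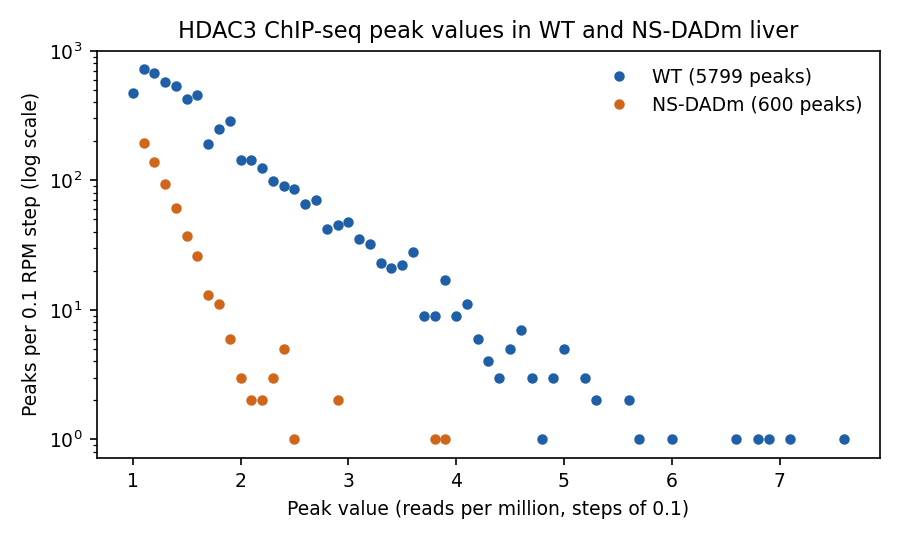
Number of HDAC3 peaks (log scale) at each 0.1 RPM step of peak value, for the WT list (5799 peaks) and the NS-DADm list (600 peaks); each point is 1 step that holds peaks. Listed NS-DADm values end at 3.9 RPM and listed WT values at 7.6 RPM.

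The peaks listed in NS-DADm liver coincided with WT peaks far more often than random positions did. Of the 600 NS-DADm peaks, 387 overlapped a WT peak, or 64.5% (95% interval 60.5 to 68.3%). Random placement gave a mean of 0.573 overlaps and at most 5 in 1000 placements. These placements were even over the span and did not allow for regions where reads gather in any library. Shifting each NS-DADm peak by 5 to 50 kb gave a mean of 4.26 and at most 14. The input was not analysed, so background gathering at the same sites in both libraries was not told apart from HDAC3. The paired summits were close, with a median distance between peak centres of 39 bp (interquartile range 14 to 73 bp). Seen from the WT list, 390 of the 5799 peaks overlapped an NS-DADm peak, or 6.73% (6.09 to 7.40%), and 5409 did not. The overlap depended on the length of the WT list: with only its 600 highest peaks, 142 NS-DADm peaks overlapped, or 23.7% (20.3 to 27.3%). Against the full WT list, the remaining 213 NS-DADm peaks had no WT peak under them.

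The WT peaks also listed in NS-DADm liver were mainly the higher ones. Shared WT peaks had a median of 2.2 RPM (interquartile range 1.6 to 2.9, 390 peaks) and WT-only peaks a median of 1.4 RPM (1.2 to 1.8, 5409 peaks). This difference of 0.8 RPM was larger than in any of the 100000 resamples of peaks (two-sided permutation p = 1e-05, the smallest they can give). The WT list was split by value into 4 parts of like size. In the highest part, from 1.9 to 7.6 RPM, 16.8% of the peaks were shared (95% interval 14.9 to 18.9%), against 5.17% (4.09 to 6.44%), 3.03% (2.21 to 4.05%) and 1.86% (1.23 to 2.70%) in the following parts. The highest part held 62.6% of all shared WT peaks. Above 4 RPM, 32 of 62 WT peaks were shared (51.6%, 38.6 to 64.5%), so that 30 of the highest WT peaks had no NS-DADm counterpart.

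**Figure D2:**
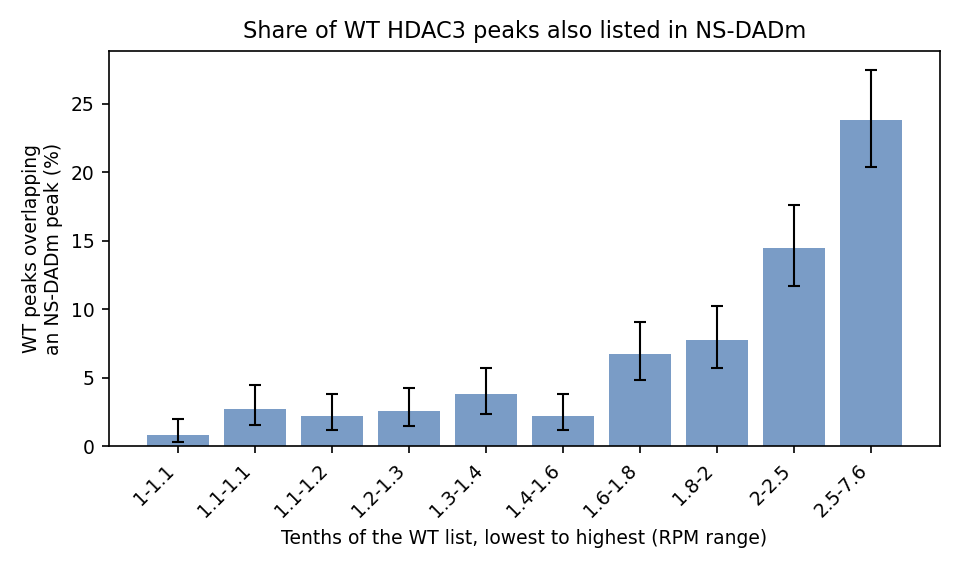
Percentage of WT HDAC3 peaks that overlap an NS-DADm peak by at least 1 bp (vertical axis) in 10 parts of like size of the WT list, ordered by RPM (horizontal axis); bars are shares and error bars exact 95% binomial intervals over peaks. The share is 0.864% in the lowest part and 23.8% in the highest.

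The 10 highest WT peaks divided evenly, 5 with and 5 without an NS-DADm peak. The highest of all, at chromosome 11, 7052505 to 7052704, had 7.6 RPM in WT, and its nearest NS-DADm peak was 40.1 kb away. The WT peaks at chromosome 15, 66843321 to 66843520 (6.6 RPM), chromosome 2, 179190375 to 179190574 (6.0 RPM), chromosome 7, 142999444 to 142999643 (5.7 RPM), and chromosome 1, 90119310 to 90119509 (5.6 RPM), likewise had no NS-DADm peak, the nearest lying 148 kb to 4685 kb away. These are also the 5 highest peaks of the WT list without a counterpart. A missing NS-DADm peak can have been under the limit or removed by another criterion, so it does not show absence of HDAC3. The first listed NS-DADm peak number was 50 on chromosome 11, 5 on 15, 12 on 2, 2 on 7 and 12 on 1. Among the 10 highest WT peaks with an NS-DADm peak, the peak at chromosome 13, 46031998 to 46032197, had 6.9 RPM in WT and 1.7 RPM in NS-DADm, a log2 ratio of -2.02. The peak at chromosome 15, 100459891 to 100460090, had 5.6 and 1.1 RPM (log2 ratio -2.35), and that at chromosome 10, 59180635 to 59180834, had 5.3 and 1.1 RPM (log2 ratio -2.27). Another WT peak tied at 5.3 RPM and was left out because ties were settled by chromosome and start. Its NS-DADm peak, at chromosome 17, 26365659 to 26365858, had 1.6 RPM (log2 ratio -1.73). Values differed less at chromosome 2, 25294710 to 25294909, with 7.1 and 2.9 RPM, and at chromosome 17, 23891298 to 23891497, with 6.8 and 3.8 RPM.

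The 5 highest NS-DADm peaks all lay on WT peaks, and each had the higher value in WT. The highest, at chromosome 8, 13159033 to 13159232, had 3.9 RPM in NS-DADm and 5.2 RPM in WT. The NS-DADm peaks on the WT peaks at chromosome 17, 23891298 to 23891497, and chromosome 2, 25294710 to 25294909, were also among these 5. At chromosome 16, 45889623 to 45889822, NS-DADm had 2.9 RPM and WT 3.5 RPM. At chromosome 4, 136320802 to 136321001, the values were 2.5 RPM in NS-DADm and 2.6 RPM in WT, a difference of a single rounding step.

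At shared peaks HDAC3 values were mostly lower in NS-DADm liver. Of the 387 pairs, 347 had the lower value in NS-DADm, 16 had equal values and 24 had the higher value in NS-DADm. The median log2 ratio of NS-DADm to WT was -0.66 (95% bootstrap interval over peaks -0.75 to -0.62), a 1.58-fold lower value. Pairs had to be listed in both lists, and the ratio depended on which list the pairs were chosen by. It was -1.0 (-1.06 to -0.95, 228 pairs) for pairs chosen by a WT value of 2 RPM or more, a choice that itself favours high WT values. At a WT value of 4 RPM or more, a subset added after seeing the data in which no pair could be higher in NS-DADm, it was -1.65 (-1.77 to -1.47, 33 pairs), or 3.14-fold lower. Counting the 38 unlisted WT peaks of that height as well, at an assumed 1.1 RPM, gave -1.86, a value largely set by that assumption. For the 17 pairs chosen by an NS-DADm value of 2 RPM or more, which favours the opposite direction and was added after seeing the data, it was -0.63 (-0.84 to -0.18), with 16 pairs lower in NS-DADm. Across the 387 pairs, which are peaks and not independent replicates, log2 values in the 2 lists had a Pearson r of 0.41 and a Spearman rho of 0.36 (permutation p = 0.0001 for each, the smallest that 10000 permutations can give). Both lists are cut near 1 RPM, and shared NS-DADm values had an interquartile range of only 1.2 to 1.4 RPM in steps of 0.1. These correlations therefore do not measure how well the 2 livers match over all sites.

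**Figure D3:**
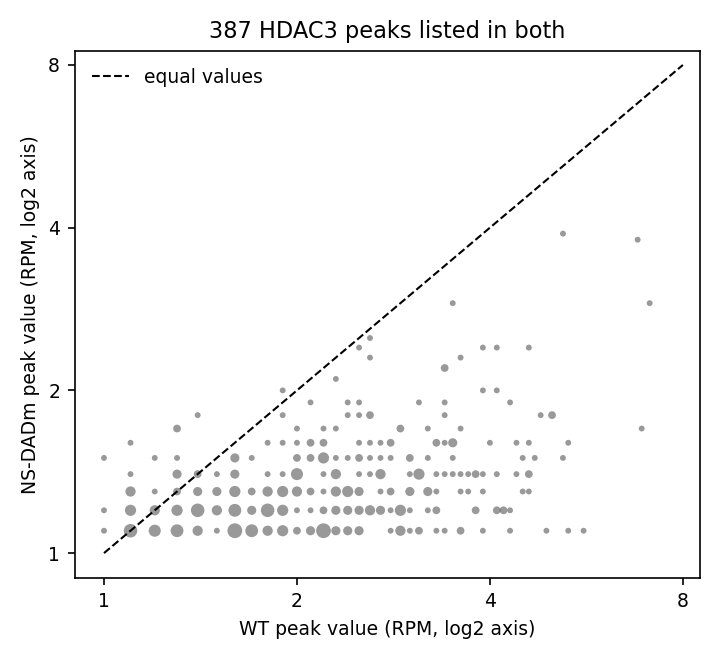
NS-DADm against WT peak value (RPM, both axes log2) for the 387 NS-DADm peaks paired with a WT peak; point size grows with the number of pairs at the same 2 values, and the dashed line marks equal values. Most points, 347 pairs, lie below the line, and 24 lie above it.

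The 213 NS-DADm peaks without a WT peak were low, by tests that were chosen after seeing the data. Their median was 1.2 RPM (interquartile range 1.1 to 1.3), against 1.3 RPM (1.2 to 1.4) for the 387 shared NS-DADm peaks, a difference of 0.1 RPM (two-sided permutation test over peaks, p = 0.0225) that equals the rounding step. They made up 51.8% of the 195 NS-DADm peaks at 1.1 RPM (44.5 to 59.0%) and 14.0% of the 50 peaks above 1.6 RPM (5.82 to 26.7%; Fisher's exact test, two-sided, p = 8.9e-07). Of the 20 NS-DADm peaks at 2 RPM or more, 17 lay on a WT peak and 3 did not. These 3 were at chromosome 11, 34525251 to 34525450 (2.4 RPM), chromosome 18, 7321382 to 7321581 (2.3 RPM), and chromosome 11, 35806938 to 35807137 (2.1 RPM), the last with a WT peak 0.79 kb away. The next in height were at chromosome 19, 5844409 to 5844608 (1.8 RPM), with a WT peak 5.57 kb away, and chromosome 1, 172881626 to 172881825 (1.7 RPM). Other NS-DADm peaks without a WT peak tied with the last at 1.7 RPM, and ties were settled by chromosome and start.

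WT peaks often lay close together. Of the 5799 WT peaks, 2811 had another WT peak within 10 kb, in 1146 clusters. The cluster with the most peaks, on chromosome 7 from 18827484 to 18859756, held 9 peaks of 1.1 to 2.8 RPM in 32.3 kb, and none of them overlapped an NS-DADm peak. Of the 37 clusters of 5 or more WT peaks, 14 had at least 1 NS-DADm overlap. Clustered peaks were shared more often than isolated ones, 7.79% (6.83 to 8.84%) against 5.72% (4.92 to 6.62%; odds ratio 1.39, Fisher's exact test, two-sided, p = 0.00194). Clustered peaks were also higher, with a median of 1.5 RPM against 1.4 RPM. Within the 4 parts of the WT list by peak value the common odds ratio was 1.08 (95% interval 0.871 to 1.34; permutation p = 0.512), so the difference did not hold among peaks of like value.

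The share of WT peaks that were also listed in NS-DADm was not distinguishable between chromosomes. Among autosomes it ran from 4.97% on chromosome 18 to 8.54% on chromosome 16. Of the 20 chromosomes tested against the others with Fisher's exact test, 0 had an adjusted p under 0.05 (lowest 0.802) and 0 an unadjusted p under 0.05 (lowest 0.220). Chromosome X had 16 WT peaks, of which 0 were shared, and 2 NS-DADm peaks. Of the 213 NS-DADm peaks without a WT peak, chromosome 11 held 24, among its 53 NS-DADm peaks, and chromosome 5 held 23, among 55. This share was not tested between chromosomes.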

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

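The tests in this part were chosen after the peak lists had been seen. Each peak's name ends in a number that runs within its chromosome, and the comparisons of peaks did not use it. Numbers are missing: 3103 numbers below the last listed one were skipped in the NS-DADm list and 5973 in the WT list, which is why the names were looked at more closely. Within chromosomes the number followed the peak value, with a median Spearman rho over peaks of -0.92 in WT (20 chromosomes) and -0.69 in NS-DADm (19 chromosomes). Over chromosomes rho ran from -0.95 to -0.82 in WT and from -0.87 to -0.43 in NS-DADm, where the order was looser. The skipped numbers may therefore be candidate peaks that ranked high enough and were removed by another criterion, although the sources used here do not say how the numbers were given. On this reading, 16.2% of the NS-DADm candidates (95% interval 15.0 to 17.4%) and 49.3% of the WT candidates (48.4 to 50.2%) were kept. In NS-DADm, 354 numbers were skipped before the first listed peak of a chromosome, most of them on chromosome 11, which starts at 50, on chromosome 9, which starts at 49, and on chromosomes Y and X, which start at 97 and 67. In WT, 38 were skipped in this way.

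For the 9.67-fold difference in peak number between the lists, the shared peaks, which pass nearly the same limit in both lists, had the lower value in NS-DADm in 89.7% of pairs (347 lower and 24 higher, exact sign test over peaks, two-sided, p = 1.6e-74). Peaks from 1 library per genotype are not independent trials, so this p-value measures no spread between libraries. If the values are scaled to library size as taken here, the lower values at shared peaks argue against greater depth of the pooled WT library alone. Greater depth would not lower the values at kept peaks. Removal by other criteria as the whole cause is argued against only if removal did not depend on peak value. The sign test cannot exclude removal that took high NS-DADm candidates more often. With the numbers read as ranks, 354 were skipped before the first listed peaks in NS-DADm and 38 in WT. Removal as part of the cause is in keeping with the lower share of numbers listed in NS-DADm, 16.2% against 49.3% (3.04-fold), with last numbers that sum to 3703 and 11772 (3.18-fold), as far as the numbers are candidate ranks and the last listed one does not itself depend on removal. A single lower scale factor for all NS-DADm peaks should keep the highest WT peaks, and 51.6% of those above 4 RPM were listed (95% upper bound 64.5%). At the 3.14-fold ratio of the 33 listed pairs with a WT value of 4 RPM or more, the lowest of them would come to 1.30 RPM. That is near the limit, where the error of a single value is unknown. Choosing pairs by a high WT value favours a large fold. The fold was 1.58 over all 387 pairs. It was 1.55 over the 17 pairs chosen by an NS-DADm value of 2 RPM or more, which favours a small fold. At these lower folds the WT peaks above 4 RPM would lie farther above the limit, which goes against such a factor alone. The fold that applies is unknown, so this does not decide. Such a factor, for example a lower immunoprecipitation yield, combined with removal or, depending on the fold, alone, therefore stays open. So do removal that depends on peak value and less HDAC3 at these sites in NS-DADm liver, since each genotype has 1 library. The WT sample pools 2 samples, 1 of them from floxed-Hdac3 liver given a virus expressing GFP. Any effect of this cannot be told apart from genotype here.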

How the results depend on the processing

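Across 46 alternatives to 11 results, 33 were counted as keeping the value or the call, 13 were not, and 0 reversed a direction. Values counted as kept could still move. Shared NS-DADm peaks went from 387 to 327 of 600 with 50% reciprocal overlap. Shared WT peaks went from 390 to 449 with a gap of up to 500 bp allowed. Many of these results are counts, which have no direction to reverse. The alternatives are not all separate checks, since overlap settings were counted once per list. With all peaks 200 bp wide, 50% reciprocal overlap and centres within 100 bp are the same rule, and both gave 327. At 2 RPM or more the lists shrank to 1222 WT and 20 NS-DADm peaks, with 16 shared peaks from either side, by construction fewer. Their ratio rose from 9.67 to 61.1, and the cause was not tested. Reducing WT to as many of its highest peaks as NS-DADm lists left 142 shared (23.7% of NS-DADm peaks against 64.5%), by construction fewer. The other overlap rules and subsets gave 327 to 406 shared NS-DADm peaks and 327 to 449 shared WT peaks, with 336 and 338 when chromosomes 9 and 11 were left out. Chance overlap rose from 0.573 to 4.26 when peaks were shifted by 5 to 50 kb (the cause was not tested), and both lie far below 387. The gap in shared percentage between the highest and lowest of 4 parts of the WT list was 15.0 points. It was 22.9 points with 10 parts, whose ends lie farther apart, and 12.4 points with a 50% reciprocal overlap, which leaves fewer shared peaks. The median log2 ratio of -0.66 became -1.0 for WT peaks at 2 RPM or more, and -1.86 over all WT peaks at 4 RPM or more with unlisted ones set at an assumed 1.1 RPM, which largely sets the value and was added later. Both choose pairs by a high WT value, and pairs chosen by the NS-DADm value gave -0.63. The odds ratio of clustered peaks fell from 1.39 to 1.08 within the 4 parts by peak value, also added later. Genes near peaks and both of their alternatives were not run, since no gene annotation of mm8 was used. No replicate could be left out, with 1 library per genotype, and rounding to 0.1 RPM limits what can be read from values near the threshold.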

Other observations

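The tests in this part were chosen after the result was seen. Chromosome X carried few HDAC3 peaks in WT liver. Its 16 peaks (95% Poisson interval 9.15 to 26.0) lay over a span of 157 Mb, or 0.102 per Mb, against 2.46 per Mb on autosomes and 1.86 per Mb on the autosome with the fewest, chromosome 14. The highest X peak had 3.1 RPM and lay at chromosome X, 165325124 to 165325323. It was chosen after its value was seen. NS-DADm liver had 2 peaks on chromosome X and 1 on chromosome Y, where WT had none.

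The single X copy of male mice may lower the reads at each X site relative to autosomes. If a 2-fold lowering were the whole cause, X should hold about as many peaks per Mb as autosomes hold at 2 RPM or more, which gives 81.5 peaks, and the interval of the observed 16 excludes this. A lower density of genes or of sites that reads can be placed on, and a true scarcity of HDAC3 sites, stay open and could not be examined without the genome of this build.

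The NS-DADm peaks without a WT overlap were not placed at random. Of these 213 peaks, 81 lay within 10 kb of a WT peak, against a mean of 8.27 and a maximum of 18 in 1000 random placements, which argues against scattered background positions. Their share fell from 51.8% at 1.1 RPM to 14.0% above 1.6 RPM (Fisher's exact test, two-sided, p = 8.9e-07). Sites near the listing threshold in NS-DADm would show such a fall. The lists give no WT value at these sites, so whether they also lay near the WT threshold was not tested. WT candidates removed by another criterion (5973 numbers were skipped in the WT list), background that gathers in the same open regions as HDAC3, and HDAC3 sites particular to NS-DADm liver, stay open.

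In the WT list 13 pairs of neighbouring peaks overlapped and 281 pairs lay within 500 bp of each other, while in the NS-DADm list these were 0 pairs and 1 pair. The last peak number on chromosome X was 44 in WT and 87 in NS-DADm, while on every autosome it was higher in WT. At 24 of the 387 shared sites NS-DADm had the higher value, the largest excess as a ratio being 1.5 against 1.0 RPM at chromosome 18, 39004822 to 39005021, a site chosen after its value was seen.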
